A study of Mus musculus with 10 samples.

How the data were processed

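The dataset held 10 liver libraries of C57BL/6 mice, 5 from wild-type (WT) animals and 5 from animals labelled Nrf2Act-hep, whose label describes NRF2 activation specific to the liver. Per the labels' protocols, the mice ate regular chow and fasted for 15 h before the livers were collected and frozen. Total RNA was made into libraries with the Lexogen QuantSeq FWD kit, which reads a short tag near the 3′ end of each polyadenylated transcript, and sequenced as single reads of 75 bases on an Illumina NextSeq 500. A tag count does not grow with transcript length, so no length correction was needed. The labels do not state that each library came from its own mouse, so p-values measure the spread between these libraries, which may be partly technical.

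The authors deposited 1 table of CPM values, in which reads are scaled to a common total per library, for 18869 gene identifiers. The build was GRCm38 per the submitters' processing notes. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. Each column summed to the total that defines the unit, and 100% of the values were whole multiples of the column's smallest value above 0, within 0.01 read. The reads behind each value were recovered from that step. They came to between 1267745 and 2287727 per WT library and between 2167528 and 2806670 per Nrf2Act-hep library. At these depths 3 reads correspond to 1.31 to 2.37 CPM in a WT library and 1.07 to 1.38 CPM in a Nrf2Act-hep library. The tags were treated as reads, not molecules, so floors and counting intervals cover counting error only. Gene symbols and coordinates came from GENCODE gene models on GRCm38. Of the identifiers, 18799 had a symbol and 70 did not.

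The design fixed before the data were examined assumed counts and named edgeR's quasi-likelihood test. Because the deposited unit is CPM, the main test was instead limma 3.58.1 with a variance trend and robust empirical Bayes moderation, run in R 4.3.3 on log2(CPM + 1) after TMM scaling with edgeR 4.0.16. The edgeR test on the recovered reads became an added alternative. Group values are means ± SD of TMM-scaled CPM. Fold changes are differences on the log2(CPM + 1) scale, which understates the change of low genes. Genes were kept if they had at least 10 reads at the median depth, equal to 4.50 CPM, in at least 5 libraries and at least 15 reads in all, which left 8075 genes. The genotype model carried the M or F letter of the sample titles as a covariate, the M against F model carried genotype, and a further model carried their interaction. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05.

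Gene lists for NRF2 targets, detoxification, growth factor signalling, liver metabolism, secreted proteins, stress, zonation, sex-biased genes and markers of other cell types were fixed before the data were examined. Of these, 41 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, then with camera at an estimated correlation and with fry. Another 6 lists had fewer. The rule for named genes was also fixed then. It took Nfe2l2 and Keap1, the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 5 CPM and no overlap between groups, and up to 4 members per list (2 with the highest mean where fewer than 2 passed). It added every growth factor ligand past the threshold, 5 autosomal genes in each direction between M and F, and up to 10 interaction genes. Unnamed gene models were left out of the named genes. Genes named in the text outside this rule are members of the fixed lists or are said to have been chosen after their values were seen.

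The tests were checked on simulated reads drawn from the real means, spreads and library sizes for 8075 genes, of which 50 were changed at each of 4 sizes. For the genotype comparison 28% of genes changed by 0.5 on the log2 scale were recovered, 76% of those changed by 1, 98% at 2 and 100% at 3, and 3.21% of the calls were false. For the interaction the recovery was 0% at 0.5, 18% at 1, 82% at 2 and 92% at 3, and 5.88% of the calls were false. For M against F 5.16% were false. Each comparison was simulated in 1 draw with genes drawn independently, so genes that move together were not covered. Alternatives planned before the data were examined were RLE size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 1 CPM in 5 libraries that keeps more genes, leaving out the 10 most abundant genes, dropping the letter term, each sex letter or genotype alone, and each library left out. Chosen after seeing the data were edgeR with TMM, the deposited scale without TMM, pseudocounts of 0.5 and 4, and the removal of both F Nrf2Act-hep or both M WT libraries. Replicate numbers run from 1 to 10 without repeats, so no pairing was fitted.

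Reads shared between near-identical paralogs could have been split by the authors' counting. Values of the Cyp2a, Gstm, Gsta, Gstp, Ugt2b, Mup, Cyp4a12, Sult2a and MHC class I genes are therefore uncertain at the level of single members. The same may hold for other gene families, such as those of Serpina1e, Cyp3a44 and Cyp2b13, which were not checked. Slc22a12 lies within the span of Nrxn2 on the opposite strand, and without a stated use of strand the reads of these genes cannot be told apart.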

Results

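Liver expression was compared between WT mice and Nrf2Act-hep mice at the age of 6 weeks, with 5 libraries per genotype. NRF2, encoded by Nfe2l2, is a transcription factor of antioxidant and detoxification genes, and KEAP1 is its repressor. The series title frames the question as whether NRF2 activates growth factor genes and AKT signalling as the liver enlarges. The sample titles carry a letter, M for WT replicates 1 and 2 and Nrf2Act-hep replicates 6 to 8, and F for WT replicates 3 to 5 and Nrf2Act-hep replicates 9 and 10. Xist was listed at 0 in all 5 M libraries and at 434.3 ± 84.0 CPM in the 5 F libraries, and the Y-linked gene Ddx3y stood at 110.7 ± 6.64 CPM in M against 0.082 ± 0.18 CPM in F, so the letters matched the sex-linked transcripts in every library.

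Recovered depth was lower in WT (median 1639434 reads, 1267745 to 2287727) than in Nrf2Act-hep (median 2306308, 2167528 to 2806670). Gm42418, a locus that overlaps ribosomal RNA sequence, took 15.7 ± 2.22% of the reads in WT and 15.0 ± 3.08% in Nrf2Act-hep (SD, n = 5 each). The mitochondrial ribosomal RNAs took 24.6 ± 2.57% and 21.7 ± 1.49%. Pairs of libraries of the same genotype correlated across genes at 0.928 to 0.962 within WT and 0.943 to 0.972 within Nrf2Act-hep, and pairs of different genotype at 0.917 to 0.946. No pair agreed within sampling noise, the lowest chi-square per degree of freedom being 4.28. The first principal component held 28.8% of the variance and followed both genotype and letter, with scores of -25.6 to -23.1 in F WT, -6.15 and -1.08 in M WT, 4.12 and 6.11 in F Nrf2Act-hep and 21.3 to 25.1 in M Nrf2Act-hep. The second held 19.1% and set M WT (23.5 and 30.6) and F Nrf2Act-hep (-15.1 and -23.1) apart at opposite ends. The F WT libraries scored -5.46 to -4.55 on it and the M Nrf2Act-hep libraries -0.89 to 0.85.

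**Figure D1:**
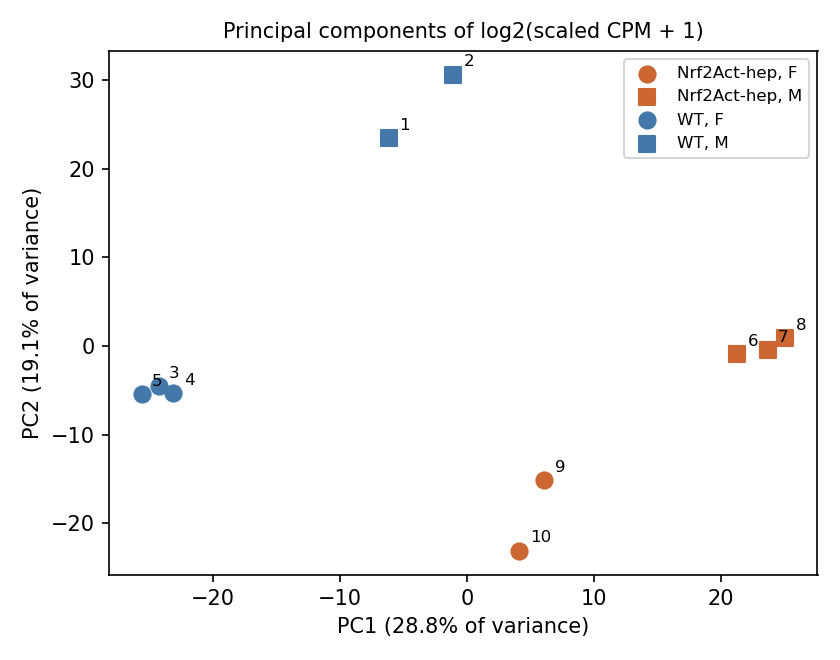
Principal components of log2(scaled CPM + 1) over 8075 genes, with the first component (28.8% of the variance) on the x axis and the second (19.1%) on the y axis. Each point is a library with its replicate number, coloured by genotype and shaped by title letter, and the WT and Nrf2Act-hep libraries do not overlap on the first component.

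The genotype comparison asked which liver transcripts differ when NRF2 is active. The gene with the largest rise was Cbr3, a carbonyl reductase, which went from 1 read in all WT libraries together to 176.2 ± 49.9 CPM in Nrf2Act-hep (limma, adjusted p = 1.44e-16; higher in 5 of 5 libraries). The ratio of its reads was 1593, with a 95% exact counting interval of 286 to 62950. Slc22a12, a urate transporter, was listed at 0 in every WT library and stood at 33.2 ± 3.09 CPM in Nrf2Act-hep (417 reads), a ratio whose 95% exact counting interval starts at 81.3. Nrxn2, whose span holds Slc22a12, rose from 1.36 ± 0.80 to 33.1 ± 8.69 CPM. The other genes among the 10 largest rises were the P450 genes Cyp2a4 (log2 fold change 3.92 ± 0.27, SE) and Cyp2a5 (3.66 ± 0.17), the glutathione transferases Gstm3 (3.69 ± 0.30) and Gsta2 (3.19 ± 0.24), the efflux pump Abcc4 (3.23 ± 0.23), Dct (3.43 ± 0.38) and the major urinary protein gene Mup17 (3.70 ± 0.80). The call of Mup17 stood at the threshold (limma, adjusted p = 0.048) and was lost without any single library except WT replicate 5 (adjusted p up to 0.15). It was also lost with no filter, with a filter of at least 1 CPM in 5 libraries, without the 10 most abundant genes and with a pseudocount of 0.5 (adjusted p up to 0.070).

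Among genes with a mean of at least 5 CPM whose library values did not overlap, the 10 largest falls had varied functions. Igf2bp3, an RNA-binding protein of fetal tissues, fell from 20.6 ± 4.56 to 3.15 ± 1.38 CPM (limma, adjusted p = 3.9e-07). The vasopressin receptor gene Avpr1a fell from 15.5 ± 3.15 to 2.12 ± 0.71 CPM (limma, adjusted p = 3.9e-07), and Igfbp2, which encodes a binding protein of insulin-like growth factors, from 304.8 ± 35.8 to 67.0 ± 22.7 CPM (limma, adjusted p = 1.14e-05). Nxpe2 (-2.11 ± 0.36), Enho (-1.73 ± 0.33), Mmd2 (-1.54 ± 0.24), the peroxisomal transporter Abcd2 (-1.51 ± 0.23), the glycolate oxidase Hao1 (-1.48 ± 0.13), Casc4 (-1.46 ± 0.29) and the antimicrobial peptide gene Leap2 (-1.45 ± 0.17) completed the 10, each lower in all 5 Nrf2Act-hep libraries than in any WT library.

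On GRCm38, Cbr3 (ENSMUSG00000022947) lies on chromosome 16 at 93683215 to 93690990, and Nqo1 (ENSMUSG00000003849) on chromosome 8 at 107388225 to 107403206. Slc22a12 (ENSMUSG00000061742) lies on chromosome 19 at 6535845 to 6543032 on the minus strand, inside Nrxn2 (ENSMUSG00000033768, 6418731 to 6544169, plus strand). Igf2bp3 (ENSMUSG00000029814) lies on chromosome 6 at 49085223 to 49214957, Avpr1a (ENSMUSG00000020123) on chromosome 10 at 122448499 to 122453452, Igfbp2 (ENSMUSG00000039323) on chromosome 1 at 72824503 to 72852474 and Nrg4 (ENSMUSG00000032311) on chromosome 9 at 55220222 to 55326844.

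In all, 225 genes were higher and 150 lower in Nrf2Act-hep among 8075 tested by limma, of which 90 and 31 changed at least 2-fold. The values of the groups did not overlap for 415 of the 8075 genes, where chance gives 0.794% of genes. On the deposited scale without TMM, the median of all genes moved from 0.0051 to 0.13 and the split became 384 higher and 80 lower, so directions are given relative to the TMM scale. The count was 245 without WT replicate 1 and 248 without Nrf2Act-hep replicate 7, and the number of lower genes was 84 without WT replicate 1 and 97 without Nrf2Act-hep replicate 10.

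Nfe2l2 itself was listed at 59.8 ± 12 CPM in WT and 40.8 ± 4.16 CPM in Nrf2Act-hep, a log2 fold change of -0.47 ± 0.13 (limma, adjusted p = 0.044) with overlapping library values. The call was lost on the deposited scale (adjusted p = 0.17), with no filter, with a filter of at least 1 CPM in 5 libraries, and without WT replicate 1, 3 or 5 or Nrf2Act-hep replicate 7, 8, 9 or 10, with an adjusted p of up to 0.145 over the fits without 1 library. The labels do not say how NRF2 was activated, and a 3′ tag of the native gene may not report an introduced or altered allele, so this value does not check the labels. Keap1 stood at 46.4 ± 3.59 and 51.4 ± 9.95 CPM (log2 fold change 0.12 ± 0.14; limma, adjusted p = 0.73).

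Known NRF2 targets rose as a group. Of 21 measured members 13 were higher and 0 lower (14 and 0 adjusted over the list alone), with a median log2 fold change of 0.80. Nqo1, a quinone reductase, rose from 3.35 ± 1.62 to 36.9 ± 13.3 CPM, the biliverdin reductase Blvrb from 47.1 ± 3.53 to 171.9 ± 18.0 CPM, the sulfiredoxin Srxn1 from 45.3 ± 13.5 to 163.0 ± 23.0 CPM, and Gclc, the catalytic subunit of glutathione synthesis, by 1.83 on the log2 scale. Hmox1 (-0.27) and Gclm (0.16) did not pass the test. The list passed camera at the preset correlation (adjusted p = 4.62e-25) and at an estimated correlation (adjusted p = 0.0053).

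Some genes of conjugation and reduction rose as well. Among 16 glutathione transferases 7 were higher and 0 lower (7 and 1 adjusted over the list alone). Gstm1 rose from 356.7 ± 124.8 to 2498 ± 687 CPM and Gstm4 from 34.1 ± 10.7 to 122.0 ± 38.0 CPM. Of 10 glucuronidation genes 7 were higher and 0 lower (10 and 0 adjusted over the list alone), among them Ugt2b35 (log2 fold change 2.02 ± 0.13) and Ugdh, which makes the UDP-glucuronate donor (1.64 ± 0.15). Of 9 genes of the pentose phosphate pathway and NADPH supply 3 were higher and 0 lower (4 and 0 adjusted over the list alone), namely Pgd (1.37 ± 0.18), Tkt (0.94 ± 0.12) and Me1 (0.56 ± 0.13). Me1 did not pass without Nrf2Act-hep replicate 10 (limma, adjusted p = 0.074). Of 15 carbonyl and aldehyde genes 6 were higher and 1 lower (7 and 1 adjusted over the list alone), with Cbr1 at 2.36 ± 0.14. All 4 lists passed camera at the preset correlation, with adjusted p = 4.93e-09, 1.35e-15, 0.0011 and 7.45e-07. With an estimated correlation only glucuronidation held (adjusted p = 0.013), and the others had adjusted p = 0.087 for glutathione transferases, 0.091 for NADPH supply and 0.19 for carbonyl genes. All 4 lists passed fry (adjusted p up to 0.00076).

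**Figure D2:**
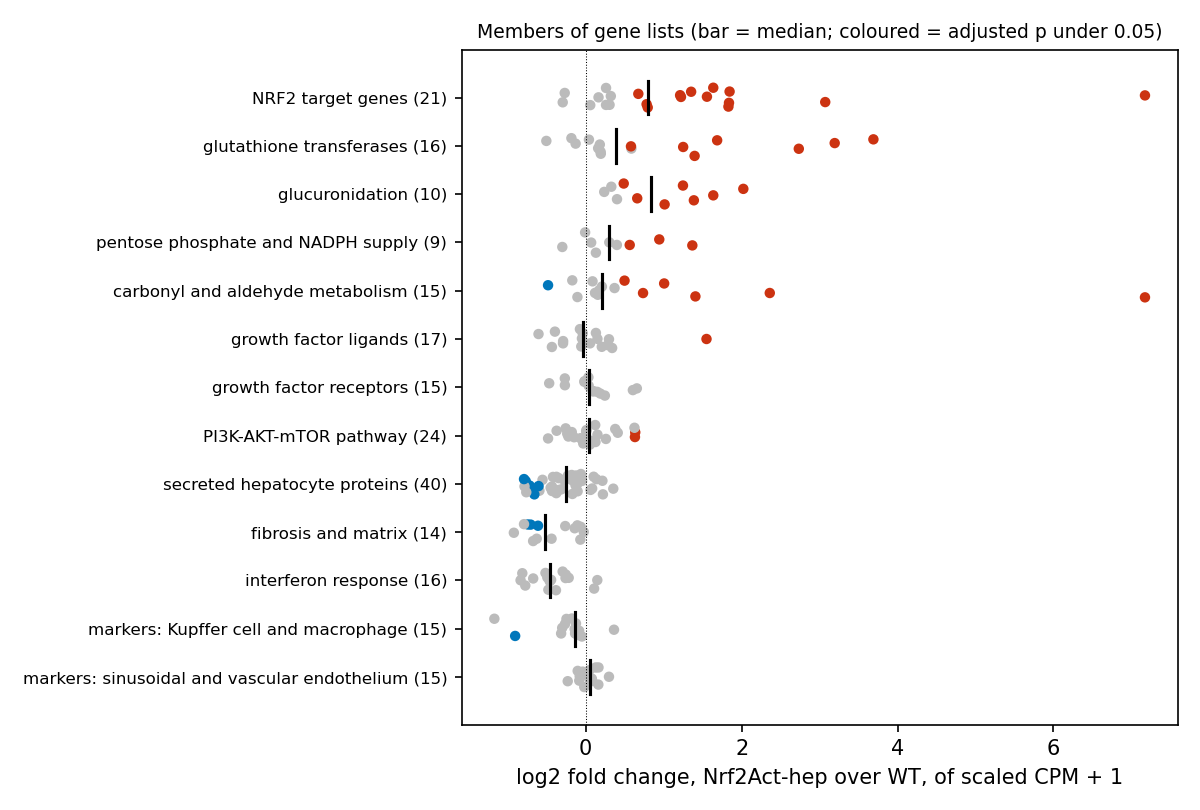
Log2 fold changes of the measured members of 13 gene lists between Nrf2Act-hep and WT (n = 5 each), with the number of measured members in brackets and a bar at the median. Each point is a gene, red or blue where limma called it higher or lower and grey otherwise. NRF2 targets have a median of 0.80, growth factor ligands of -0.04 and matrix genes of -0.52. On the deposited scale without TMM, which is not drawn, these medians were 0.93, 0.08 and -0.40.

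The drug and bile transporters held 5 higher and 1 lower of 17 (7 and 4 adjusted over the list alone), and the list as such did not pass camera (adjusted p = 0.069) but passed fry (adjusted p = 0.0058). The efflux pumps Abcc3 (log2 fold change 1.31 ± 0.19) and Abcg2 (1.01 ± 0.13) rose with Abcc4, and the bile salt pump gene Abcb11 fell from 90.4 ± 11.5 to 45.7 ± 11.6 CPM. Among 32 P450 and xenobiotic receptor genes 7 were higher and 2 lower (7 and 3 adjusted over the list alone), with Cyp1a2 rising from 332.8 ± 113.7 to 948.5 ± 208.8 CPM. Cyp3a11, a drug-metabolising member, fell from 3089 ± 1357 to 572 ± 458 CPM (log2 fold change -2.55 ± 0.55; limma, adjusted p = 0.046) with overlapping library values. Its call was lost with edgeR, with no filter, with a filter of at least 1 CPM in 5 libraries and on the deposited scale (adjusted p up to 0.080). It was also lost without WT replicate 1, 2, 3 or 4 or Nrf2Act-hep replicate 6, 7, 8 or 10 (adjusted p up to 0.14). In the M libraries alone the log2 fold change of Cyp3a11 was -3.62 (limma, adjusted p = 2.65e-11), and in the F libraries alone -1.49 (adjusted p = 0.59). Its interaction did not pass. This list passed camera at the preset correlation (adjusted p = 0.012), but with an estimated correlation the adjusted p = 0.40, and it did not pass without WT replicate 2 (adjusted p = 0.080) or Nrf2Act-hep replicate 9 (adjusted p = 0.10). Of 25 iron and haem genes 4 were higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0080, and adjusted p = 0.20 with an estimated correlation). They included the haem transporter Slc48a1 (1.35 ± 0.14) and the ferritin light chain Ftl1 (0.78 ± 0.14).

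Growth factor ligands, the subject of the series title, were then tested. Of 40 listed ligands 17 passed the filter, and 1 was higher and 0 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.88). The ligand that passed was Nrg4, a neuregulin, at 7.48 ± 4.64 CPM in WT and 19.2 ± 12 CPM in Nrf2Act-hep (log2 fold change 1.55 ± 0.35; limma, adjusted p = 0.019). Its library values overlapped, and the call was lost with edgeR, limma-voom or no letter term and without WT replicate 1 or 2 or Nrf2Act-hep replicate 7 or 10 (adjusted p up to 0.076 over the fits without 1 library and up to 0.30 over the other settings). In the M libraries alone Nrg4 had a log2 fold change of 2.19 (limma, adjusted p = 0.00075), and in the F libraries alone of 0.91 (adjusted p = 0.48). Its interaction did not pass. Igf1 stood at 545.1 ± 139.0 and 562.3 ± 106.7 CPM (log2 fold change -0.05 ± 0.12, and 0.06 with no letter term; limma, adjusted p = 0.89), and Fgf1 at 83.0 ± 6.20 and 62.9 ± 6.62 CPM (-0.39 ± 0.12; limma, adjusted p = 0.068).

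Among 16 ligands below the filter with at least 10 reads, 0 passed an exact two-sided permutation test after Benjamini-Hochberg adjustment. This test was chosen after the data were seen and took no account of the letter. Fgf21, a fasting hormone of the liver, had 15 reads in WT and 66 in Nrf2Act-hep (1.96 ± 0.93 and 5.14 ± 2.15 CPM; exact permutation p = 0.016, adjusted p = 0.13). Pdgfc had 16 and 44 reads (2.00 ± 0.59 and 3.59 ± 1.36 CPM; exact permutation p = 0.024, adjusted p = 0.13), and Vegfd had 2 and 12. Counted at an unadjusted exact p under 0.05, 4 of the 16 passed, the other being Vegfc, which was lower in Nrf2Act-hep (12 and 9 reads). The smallest p that 5 libraries against 5 can give is 0.0079, so a single ligand could not have passed among 16 and the test does not show that these ligands were unchanged.

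Growth factor receptors held 0 higher and 0 lower of 15 by limma (0 and 0 adjusted over the list alone; camera adjusted p = 0.73). In the PI3K-AKT-mTOR list 2 of 24 were higher and 0 lower (3 and 1 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.55). These were the kinase gene Mtor, at 29.9 ± 4.45 and 46.2 ± 8.68 CPM (log2 fold change 0.64 ± 0.15; limma, adjusted p = 0.012), and the translation repressor Eif4ebp1, at 15.2 ± 2.34 and 23.7 ± 4.25 CPM (0.63 ± 0.17; limma, adjusted p = 0.037). Mtor did not pass without WT replicate 1 or Nrf2Act-hep replicate 10 (adjusted p up to 0.088). Eif4ebp1 did not pass with DESeq2, with no letter term, or without WT replicate 2, 3 or 4 or Nrf2Act-hep replicate 6, 7, 9 or 10 (adjusted p up to 0.16). Transcript levels do not measure phosphorylation of AKT. Of 40 cell cycle genes 5 passed the filter, and 0 were called by limma (0 and 1 adjusted over the list alone). The summed signal of this list was 110.8 ± 13.1 CPM in WT and 94.2 ± 9.70 CPM in Nrf2Act-hep (exact permutation p = 0.071, adjusted p = 0.14). This permutation took no account of the letter, which is unbalanced between the genotypes.

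**Figure D3:**
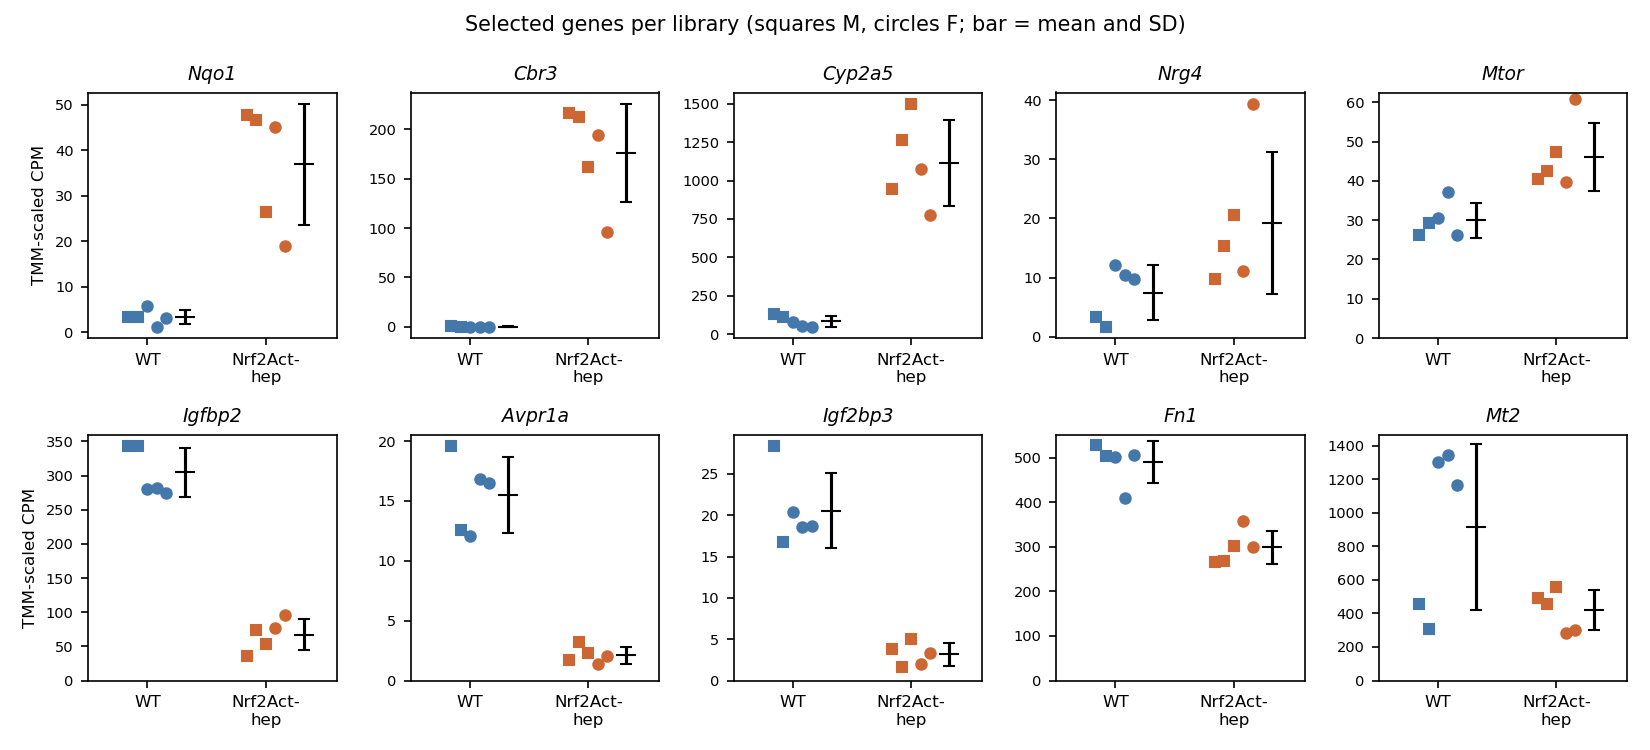
TMM-scaled CPM of 10 named genes in each library, squares for M and circles for F, with the mean and SD of the 5 libraries of each genotype as a bar. Values of Nqo1, Cbr3, Cyp2a5, Mtor, Igfbp2, Avpr1a, Igf2bp3 and Fn1 do not overlap between genotypes, those of Nrg4 do, and Mt2 is highest in the 3 F WT libraries (1163 to 1342 CPM).

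Some genes of plasma proteins and of extracellular matrix fell. Of 40 secreted hepatocyte proteins 0 were higher and 6 lower (0 and 17 adjusted over the list alone), with a median log2 fold change of -0.25. Apoa1 fell from 8164 ± 1305 to 4854 ± 632 CPM and Ahsg, which encodes fetuin-A, from 10105 ± 887 to 6134 ± 684 CPM. Of 14 matrix genes 0 were higher and 3 lower (0 and 5 adjusted over the list alone), all 14 had fold changes below 0, and the median was -0.52. Sparc fell from 201.6 ± 18.9 to 122.6 ± 13.5 CPM and Fn1, which encodes fibronectin, from 490.4 ± 47.0 to 298.8 ± 37.4 CPM. Both lists passed camera at the preset correlation (adjusted p = 1.47e-07 and 1.47e-05), and with an estimated correlation the adjusted p = 0.27 and 0.20. With fry the adjusted p was 0.049 and 0.037. On the deposited scale the medians were -0.12 and -0.40, with 2 genes lower in each list. The matrix list also passed camera for the interaction at the preset correlation (adjusted p = 0.0072, median 0.38, F minus M). At an estimated correlation that adjusted p was 0.69. Fitted apart, Fn1 had a log2 fold change of -0.89 in M and -0.52 in F, and Sparc of -0.77 and -0.72.

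Of 19 acute phase genes 0 were higher and 2 lower (0 and 3 adjusted over the list alone), with Hp falling from 4087 ± 362 to 2542 ± 204 CPM. The list passed camera at the preset correlation (adjusted p = 0.049), with adjusted p = 0.40 at an estimated correlation, and did not pass without WT replicate 1 or 5 or Nrf2Act-hep replicate 6, 9 or 10 (adjusted p up to 0.24). Of 16 interferon response genes 0 were higher and 0 lower by limma (0 and 3 adjusted over the list alone), with 2 fold changes above 0 and a median of -0.45. That list passed camera (adjusted p = 0.00026), with adjusted p = 0.38 at an estimated correlation.

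Metabolic lists were mixed. Of 18 cholesterol genes 5 were higher and 0 lower (7 and 0 adjusted over the list alone; camera adjusted p = 5.56e-06, and adjusted p = 0.35 with an estimated correlation). Lss, the lanosterol synthase, rose from 7.35 ± 1.26 to 17.7 ± 5.98 CPM. Msmo1, Sqle and Cyp51 passed with their highest values in Nrf2Act-hep replicate 9 (116.7, 34.6 and 93.8 CPM, against at most 48.1, 11.1 and 46.6 CPM in the other Nrf2Act-hep libraries). Their calls were lost with limma-voom and with no letter term. Msmo1 and Sqle were also lost with edgeR under TMM or RLE factors. Msmo1 and Cyp51 were lost with no filter, and Sqle with a pseudocount of 4. Over these settings the adjusted p reached 0.16 for Msmo1, 0.23 for Sqle and 0.11 for Cyp51. Without 1 library, Msmo1 was lost for any WT replicate and Nrf2Act-hep replicate 6, 7 or 8, Sqle for WT replicate 2, 3, 4 or 5 and Nrf2Act-hep replicate 6, 7 or 9, and Cyp51 for WT replicate 1, 2 or 5 and Nrf2Act-hep replicate 6, 7 or 8 (adjusted p up to 0.11, 0.19 and 0.13). Of 22 stress response genes 4 were higher and 0 lower (8 and 2 adjusted over the list alone; camera adjusted p = 9.63e-05, and adjusted p = 0.20 with an estimated correlation), with the endoplasmic reticulum factor Manf rising by 0.91 on the log2 scale. Of 41 urea cycle and amino acid genes 2 were higher and 3 lower (2 and 6 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.62 with an estimated correlation, and 0.097 without WT replicate 1). Agxt fell by 0.93 on the log2 scale and the transaminase Gpt2 rose by 0.64. Bile acid synthesis held 2 higher and 2 lower of 18 (2 and 3 adjusted over the list alone, camera adjusted p = 0.88), with Cyp7b1, an oxysterol hydroxylase, rising from 7.56 ± 3.83 to 67.5 ± 46.3 CPM. These means pool the letters, and WT held fewer M libraries. With the letter in the model its log2 fold change was 2.32 to 2.58 over the fits without 1 library. It was 2.92 in the M libraries alone and 2.00 in the F libraries alone. In the fatty acid synthesis list 3 were higher and 1 lower of 21 (3 and 1 adjusted over the list alone; camera adjusted p = 0.88), with the fatty acid transporter Cd36 rising from 96.8 ± 18.3 to 282.7 ± 48.5 CPM. In the fatty acid oxidation list 2 were higher and 2 lower of 32 (2 and 3 adjusted over the list alone; camera adjusted p = 0.52).

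Zonation and marker lists were compared as well. Of 21 pericentral genes 2 were higher and 1 lower (2 and 1 adjusted over the list alone; camera adjusted p = 0.0040, adjusted p = 0.20 with an estimated correlation, and 0.052 without Nrf2Act-hep replicate 9), and the higher ones were Cyp2a5 and Cyp1a2. Of 24 periportal genes 3 were higher and 1 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.69). Endothelial markers had a median log2 fold change of 0.05 over 15 genes (camera adjusted p = 0.88), stellate cell markers of -0.12 over 13 (camera adjusted p = 0.11) and Kupffer cell markers of -0.14 over 15. On the deposited scale the endothelial median was 0.17, the stellate median 0.01 and the Kupffer median -0.02. The Kupffer list passed camera (adjusted p = 0.017, and adjusted p = 0.27 with an estimated correlation), and did not pass without WT replicate 2 (adjusted p = 0.059) or Nrf2Act-hep replicate 7 (adjusted p = 0.062). Cholangiocyte markers had 4 measured members with 1 lower, the hepatic transcription factor Onecut1 at -1.28 ± 0.27 (camera adjusted p = 0.040, adjusted p = 0.32 with an estimated correlation). The camera call of this list, not that of Onecut1, was lost without WT replicate 1 or 4 or Nrf2Act-hep replicate 6, 8 or 10 (adjusted p up to 0.15). Summed neutrophil markers were 45.9 ± 37.4 CPM in WT and 15.4 ± 1.83 CPM in Nrf2Act-hep, summed B and plasma cell markers 15.6 ± 4.26 and 26.1 ± 6.31 CPM, and summed pancreas markers 35.0 ± 30.6 and 8.69 ± 2.86 CPM. The exact permutation p of these sums was 0.048, 0.0079 and 0.024, and adjusted over 12 lists 0.11, 0.048 and 0.071. Among the same 12 lists the summed matrix genes were 1368 ± 121 CPM in WT and 978 ± 72.3 CPM in Nrf2Act-hep (exact permutation p = 0.0079, adjusted p = 0.048). These permutations took no account of the letter. In the B and plasma list 1 gene passed the filter, Igkc (log2 fold change 1.22). It stood at 3.18 to 7.55 CPM in WT and 9.25 to 19.8 CPM in Nrf2Act-hep. Members below the filter were mixed, with Jchain at 17 reads in WT and 53 in Nrf2Act-hep, but Cd79b at 8 and 6 and Mzb1 at 6 and 5. The sum therefore does not show a rise across the list. Fitted apart, S100a8 had a log2 fold change of -0.06 in M and -2.10 in F and S100a9 of 0.08 and -1.97, but their interaction did not pass (limma, adjusted p = 0.36 and 0.44), and WT replicate 5 was highest (45.0 and 40.1 CPM).

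The remaining lists did not pass camera between the genotypes. Glycolysis and glycogen held 2 higher and 1 lower of 18 (adjusted p = 0.16), with the glycogen branching enzyme Gbe1 at 1.00 ± 0.15. FOXO and fasting genes held 1 higher and 1 lower of 20 (adjusted p = 0.88), the circadian clock 0 and 2 of 15 (adjusted p = 0.47), autophagy and lysosome 1 and 0 of 31 (adjusted p = 0.16), YAP targets 1 and 0 of 10 (adjusted p = 0.73), fetal and liver tumour genes 1 and 1 of 5 (adjusted p = 0.88) and erythroid markers 1 and 0 of 6 (adjusted p = 0.32). In that fetal list Ly6d rose from 8.39 ± 4.54 to 49.5 ± 13.7 CPM. Proteasome genes (33 measured; adjusted p = 0.62), p53 targets (11; adjusted p = 0.92), serine, one-carbon and purine genes (11; adjusted p = 0.73) and monocyte and dendritic cell markers (5; adjusted p = 0.37) held 0 genes called by limma. Camera at the preset correlation called 18 of 41 lists by genotype, camera with an estimated correlation 2 and fry 12. Lists that passed fry and are not given above were NRF2 targets (adjusted p = 4.79e-06), iron and haem (0.0026), pericentral (0.019), stress (0.024) and P450 genes (0.028). Called by camera but not by fry were cholangiocyte (0.082), Kupffer (0.089), cholesterol (0.11) and male-biased genes (0.15). So were interferon (0.17), acute phase (0.18) and urea cycle genes (0.36).

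The M against F comparison described sex-linked differences with genotype in the model. The sulfotransferase Sult2a1 stood at 0.17 ± 0.23 CPM in M and 231.5 ± 168.4 CPM in F (log2 difference, F minus M, 7.15 ± 0.46; limma, adjusted p = 2.41e-05), and Sult3a1 at 1.73 ± 1.69 and 119.7 ± 135.5 CPM (5.38 ± 0.38). Cyp2b13 (3.95 ± 0.34), Cyp3a44 (3.94 ± 0.34) and Sult2a5 (3.79 ± 0.31) were also higher in F. The fatty acid hydroxylase Cyp4a12a was higher in M, at 374.9 ± 260.3 against 3.95 ± 2.41 CPM (-5.71 ± 0.61; limma, adjusted p = 0.0051), with Cyp4a12b (-5.24 ± 0.51), Serpina1e (-3.84 ± 0.62), Mup20 (-3.77 ± 0.26) and Mup21 (-3.04 ± 0.41). In all, 46 genes were higher and 48 lower in F. The count was 57 without WT replicate 2 and 147 without Nrf2Act-hep replicate 9. Of 15 genes listed as male-biased 12 were lower and 0 higher in F (15 and 0 adjusted over the list alone), and of 20 listed as female-biased 8 were higher and 0 lower (13 and 0 adjusted over the list alone). Both lists passed camera at the preset correlation (adjusted p = 3.99e-44 and 9.73e-28) and at an estimated correlation (adjusted p = 0.0085 and 0.0020). Another 9 lists passed camera at the preset correlation and not at an estimated one. NRF2 targets (adjusted p = 0.00014, and 0.14 estimated), carbonyl genes (6.47e-07 and 0.14), glucuronidation (1.58e-06 and 0.086), glutathione transferases (0.046 and 0.44) and cholangiocyte markers (0.0024 and 0.14) leaned lower in F. FOXO and fasting genes (2.98e-09 and 0.086), fatty acid synthesis (0.0029 and 0.14), fatty acid oxidation (0.014 and 0.27) and cholesterol genes (0.0058 and 0.51) leaned higher. The glutathione transferase call was lost without WT replicate 1 or 5 or Nrf2Act-hep replicate 6, 7, 8 or 10 (camera, adjusted p up to 0.44), that of fatty acid oxidation without WT replicate 1 or 4 (up to 0.12) and that of cholesterol genes without Nrf2Act-hep replicate 9 (0.77).

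Between the genotypes the male-biased list held 5 higher and 2 lower of 15 (5 and 3 adjusted over the list alone), including the hydroxylase Cyp7b1, also named above. The camera adjusted p of the list was 0.040, with adjusted p = 0.62 at an estimated correlation. The call was lost without WT replicate 1, 2 or 5 or Nrf2Act-hep replicate 7 or 8 (adjusted p up to 0.28). For the interaction, F minus M, the list passed camera at the preset correlation (adjusted p = 4.49e-07, median -0.92). It did not at an estimated correlation (adjusted p = 0.67), 3 of the 15 values lay above 0, and 0 genes passed by limma. Fitted apart, Mup21 had a log2 fold change of 2.53 in M and 0.86 in F, and Serpina1e of -1.35 and -4.32. The pooled counts may therefore not hold alike for both letters. The female-biased list held 2 higher and 1 lower of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.73).

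The interaction asked whether the genotype difference depended on the letter, and 2 genes passed by limma, with 576 at an unadjusted p under 0.05. The metallothionein gene Mt2, on chromosome 8 at 94172664 to 94173568, stood at 1269 ± 93.7 CPM in F WT (n = 3) against 294.1 ± 11.3 CPM in F Nrf2Act-hep (n = 2), and at 381.5 ± 106.4 CPM in M WT (n = 2) against 502.6 ± 51.0 CPM in M Nrf2Act-hep (n = 3). The difference of the genotype effects, F minus M, was -2.52 ± 0.26 on the log2 scale (limma, adjusted p = 2.33e-05). The linker histone gene Hist1h1c, on chromosome 13 at 23738808 to 23740367, stood at 256.7 ± 48.7 CPM in F WT, 79.4 ± 4.27 CPM in F Nrf2Act-hep, 80.3 ± 16.5 CPM in M WT and 101.2 ± 22.2 CPM in M Nrf2Act-hep (-1.99 ± 0.28; limma, adjusted p = 0.0029). Without WT replicate 2 Hist1h1c did not pass (limma, adjusted p = 0.094), DESeq2 called 15 genes, and the count without 1 library ran from 1 to 12. Of 41 lists 7 passed camera for the interaction at the preset correlation, and 0 at an estimated correlation or with fry. The interaction, F minus M, was negative for the male-biased list (camera, adjusted p = 4.49e-07). So it was for acute phase (0.016), erythroid (0.019), urea cycle (0.020) and fetal genes (0.040). It was positive for matrix (0.0072) and interferon genes (0.031), whose genotype medians lay below 0. Fitted apart, the M libraries gave 250 genes by genotype and the F libraries 130, and 68 genes were called in both, all with the same sign, where independent lists would share 1.65 higher and 0.52 lower genes.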

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

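The tests of matrix genes against cell markers and the tests of Mt2 and Hist1h1c apart for a single unusual library were chosen only after the results were seen, and so was the number of thinning draws, which was set when single draws gave different counts.

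The genes called by genotype were weighed against chance and depth. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 1 gave as many genes as the 375 of the real split. The highest other split gave 5. Here and in the splits below, the other splits kept the real difference in their spread, which can lower their counts. The test therefore makes a chance split unlikely, at 1 in 100, but does not exclude it or anything else that runs with genotype. WT libraries were shallower, and when every library was thinned to 1267745 reads in 20 draws, the median was 300.5 genes (281 to 323), of which 278 were also called at full depth. The depth difference alone therefore does not account for the calls. For M against F, 1 of 100 splits gave as many as 94 genes, the highest other being 24. For the lists, 1 of 100 splits gave as many as the 18 called by genotype (highest other 15, median of the others 5), but 17 of 100 gave as many as the 11 called between M and F (highest other 15), so chance could explain that count of lists.

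The 2 genes whose genotype difference depended on the letter were Mt2 (-2.52 on the log2 scale, F minus M) and Hist1h1c (-1.99). Both differences rest on high values in the 3 F WT libraries. After thinning every library to the depth of the shallowest, the larger adjusted p of the interaction of both genes reached at most 0.015 in 20 draws (limma), which argues against depth. An unusual single library does not account for Mt2, since its adjusted p reached at most 0.000675 whichever library was left out. For Hist1h1c it cannot be told apart, since leaving out WT replicate 2, which leaves a single M WT library, gave an adjusted p of 0.094. The difference itself stayed between -2.20 and -1.78 in all 10 fits, so what keeps this open is the p-value, not the size. A genotype effect that differs between male and female mice stays open as an untested biological explanation.

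The lower matrix genes were set against a change in cell types. A lower share of all non-hepatocyte cells would lower endothelial markers alike, but their median lay 0.57 above that of the matrix list (95% bootstrap interval of the difference of medians 0.13 to 0.76). The bootstrap intervals here resample the genes of each list, not the libraries. They hold no spread between libraries and treat genes that move together as separate, so they cannot exclude a change in cell types. Kupffer cell markers were lower, with a median of -0.14 (interval -0.27 to -0.098), but of only -0.02 on the deposited scale, so a lower share of Kupffer cells is neither shown nor excluded. Fewer stellate cells would lower stellate markers, but the 8 outside the matrix list had a median 0.49 above it (interval 0.043 to 0.70). That lower bound lies close to 0. A first version of the test, which compared the intervals of the medians (-0.16 to 0.05 for stellate markers and -0.71 to -0.11 for the matrix list), left this explanation open because they overlapped, and it was replaced after its result was seen, so the evidence against fewer stellate cells is weak. Lower expression of matrix genes per cell may account for the pattern, as a hypothesis that counting cells would test. Which cells of the liver the matrix transcripts came from, those of Fn1 included, was not tested. That list's call was lost with an estimated correlation (adjusted p = 0.20).

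Single libraries stood apart from the other 4 of their genotype in 21 of 280 groups of values tested. Chance gives about 14 if the groups are independent and hold no difference between M and F, but the test pooled the letters. Of the 21, 6 fell on Nrf2Act-hep replicate 9, which with replicate 10 makes up the F libraries of that genotype. Nrf2Act-hep replicate 10 held 8. It was low for the NRF2-linked genes Gstm3 (54.2 CPM, others 130.8 to 155.7), Gsta2 (31.2, others 60.7 to 70.3) and Abcc4 (23.0, others 37.0 to 43.4), low for Krt8 (15.2 CPM) and Cry1 (0.82 CPM), and high for Nfe2l2 (48.0 CPM), Gadd45b (59.9 CPM) and Trp53inp1 (222.1 CPM, others 50.7 to 69.3). Nrf2Act-hep replicate 9 was high for Cyp3a11 (1387 CPM, others 292.0 to 405.5), Abcb11 (65.9 CPM) and Fabp1 (1864 CPM), low for Etnppl (145.3 CPM) and Apoa1 (3764 CPM), and had the most reads (2806670). In WT, replicate 1 held the single Cbr3 read (0.68 CPM) and the highest Clu (1141 CPM), replicate 2 was high for Tkt (41.0 CPM) and low for Wipi1 (26.8 CPM), and replicate 4 was low for Abcd2 (33.7 CPM) and Fn1 (408.8 CPM). Nxpe2 was listed at 0 in Nrf2Act-hep replicate 6.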

How the results depend on the processing

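Settings planned before the data were examined and those added afterwards, namely edgeR with TMM, the deposited scale, pseudocounts of 0.5 and 4 and the removal of both libraries of a letter, left the sign of each named gene call in place. Of 100 named genes called by genotype, 72 were called under all 11 processing settings and 66 in all 10 fits without 1 library. The 375 genes called became 374 with edgeR, 373 with RLE factors, 366 with DESeq2 and 360 with limma-voom, sharing 356, 355, 331 and 345 genes with the 375. On the deposited scale 384 were higher and 80 lower, which follows from the higher TMM factors of Nrf2Act-hep. With fewer libraries the counts fell: M alone gave 88 lower genes, F alone 130 genes (82 higher, 48 lower), removal of both F Nrf2Act-hep libraries 211 (144 and 67) and of both M WT libraries 170 (106 and 64). Nrf2Act-hep alone gave 58 genes between M and F. The interaction gave 15 genes with DESeq2 and 18 with no filter, and the cause was not tested. An estimated correlation left 2 lists by genotype and 2 between M and F, and the cause was not tested. Without 1 library, genotype gave 245 to 345 genes (147 to 205 higher, 84 to 152 lower), M against F 57 to 147, the interaction 1 to 12, and the lists 15 to 18 and 11 to 15. Of the ligands, 16 had at least 10 reads but missed the filter. Among genes that passed it, those changed by 0.5 (log2) were recovered in 28% of simulated genotype cases.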

Other observations

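The values below were chosen after they were seen. MHC class I genes on chromosome 17 went apart. H2-K1 was lower in Nrf2Act-hep, at 519.6 ± 61.2 CPM in WT and 287.2 ± 35.3 CPM in Nrf2Act-hep (limma, adjusted p = 8.03e-05), as were H2-Q7 (23.6 ± 4.39 and 8.42 ± 3.07 CPM) and H2-Q10 (477.5 ± 82.4 and 278.7 ± 26.5 CPM), while H2-D1 was higher (190.9 ± 20.8 and 269.3 ± 36.0 CPM; limma, adjusted p = 0.023). The light chain gene B2m stood at 1731 ± 182 and 1914 ± 204 CPM (limma, adjusted p = 0.68). These genes share sequence, how their reads were assigned is not given in the sources used here, and a strain variant at these genes could not be checked.

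The near-identical genes Cyp2a4 and Cyp2a5 rose together by genotype and went apart by letter. Cyp2a4 stood at 8.32 CPM in M WT, 48.3 in F WT, 232.9 in M Nrf2Act-hep and 449.7 in F Nrf2Act-hep. Cyp2a5 stood at 119.2, 58.2, 1238 and 926.6 CPM in the same order.

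Some NRF2-linked genes that missed the filter had more reads in Nrf2Act-hep. The cystine transporter Slc7a11 had 8 reads in WT and 34 in Nrf2Act-hep, Gsta1 had 1 and 18, and Mgst3 had 13 and 64, against 8586006 and 11878859 reads in all. These were not tested.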
